A study of Danio rerio with 20 samples.

How the data were processed

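Messenger RNA was measured by RNA sequencing in 20 libraries of cells from the spinal cord of adult zebrafish. The fish carry a green fluorescent reporter under control of the olig2 gene, which is active in the oligodendrocyte lineage. Whether the reporter also marked other cells was not tested. Per the labels, 10 libraries came from fish 7 days after the cord was cut and 10 from sham-operated fish whose cord was left intact. The labels' protocols state that 9 cords were taken per group, as pieces of about 0.5 mm just rostral of the injury or from the matching place in shams. The pieces of a group were dissociated together and living reporter-positive cells were sorted. The 10 libraries of a group may therefore be portions of 1 pool of cells, and p-values measure only the spread between these libraries, which may be technical. The number of cells in a library, the library kit and any use of molecular identifiers are not given in the sources used here. Intervals and floors cover counting error only.

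The authors deposited 1 table of read counts per gene. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1, aligned with GSNAP 2018-05-30 to zebrafish build GRCz10 and counted with featureCounts 1.6.2. Per the file headers, the annotation was Ensembl release 87, reads with a mapping quality of at least 1 were counted, and the strand setting was 0, so that strand was ignored. Counts of overlapping genes on opposite strands therefore cannot be told apart, and reads shared by near-identical copies may be divided between them or lost. The deposited table also gives each gene's exon length, which was not used here. It has 32358 rows, of which 92 are spike-in sequences with 2 counts in all libraries together; these were left out. The remaining 32266 rows are Ensembl genes, 23989 of them with a count in some library. Each of the 20 columns was matched to its sample by the sample title.

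Symbols come from a table that pairs Ensembl identifiers with names, which covers 26433 of the genes. It writes many zebrafish genes in capitals, and such symbols are printed as that table gives them. Where 2 genes share a symbol, the identifier is printed. Before the data were examined, 32 gene lists with 1310 symbols were fixed, 20 for pathways and 12 for cell types. They matched 1315 gene entries, 907 by the same symbol, 38 by a synonym from RefSeq names of assembly GRCz12tu and 370 by the symbol without its paralog letter. There were 68 listed symbols without a match, 3 of them because more than 3 genes carry the symbol and 3 because the symbol names an unrelated gene.

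Library totals ran from 7134670 to 10264810 counts, so that 3 counts in a sham library correspond to 0.37 CPM on average (CPM, counts scaled to a common library total). That level served as the floor for genes with no count in any sham library. For such genes a fold is printed as a lower bound against the floor, and for genes with 1 to 3 sham counts as a ratio of summed counts with a 95% exact binomial interval. Levels are CPM on library sizes scaled by the trimmed mean of M values (TMM), given as mean ± SD with n = 10 per group unless stated.

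The comparison of lesion with sham used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM, a negative binomial quasi-likelihood fit with the group as its only term and the F test, with Benjamini-Hochberg adjustment over the 10467 genes tested and a threshold of 0.05. All p-values from this test are two-sided. Standard errors are the absolute log2 fold change divided by the square root of F. Lists with at least 5 tested members, 24 of them, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. The lists below that size are reported as counts only. Detected genes, totals and shares of counts were compared by two-sided permutation tests of the difference in means with 100000 resamples, over 7 measures, with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

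Named genes follow a rule fixed before the data were examined: 9 lineage, myelin and proliferation genes; the 10 largest changes in each direction among genes with an adjusted p under 0.05, a count in at least 8 libraries of the higher group and a symbol that is not a clone name; up to 4 members of each list with the smallest p; and the 5 most abundant genes of each group. The text names part of these.

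The test was tried on simulated counts drawn from the means and dispersions of the 20 libraries, with 200 changed genes among 9668 tested. It recovered 3 of 67 genes changed 2-fold, 31 of 67 changed 4-fold and 50 of 66 changed 16-fold, and 2 of its 86 calls were false. Small changes are therefore mostly missed at this spread. In simulated libraries with no change it called 0 genes and 0 of 24 lists. The simulated genes were drawn independently, so that this does not try the list test under correlation between genes.

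Alternatives fixed before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma-voom with quality weights, a robust fit, the row letter in the sample titles or the number of detected genes as a covariate, thinning to 7134670 counts per library, each row letter alone, each library left out, and stricter thresholds. The titles end in what look like plate positions. Rows A and B hold 6 and 4 libraries of each group, whereas columns do not overlap between the groups, so that a plate column and the lesion cannot be told apart. After the data were seen, fits without lesion replicates 2, 9 and 10, or with those 3 summed, were added. No library met the rule for too few counts or genes, so that the fit without such libraries does not apply. Replicate numbers follow the order of the samples and pair nothing. Some genes that the rule for naming genes would select are not reported here.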

Results

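The series compared reporter-positive cells from the cord of fish 7 days after a spinal lesion with those of sham-operated fish, and the labels call these cells oligodendrocyte progenitor cells. The fish regrows axons and recovers function after such a lesion, and the comparison asks which genes these cells express at other levels while that happens. There were 10 lesion libraries with 8404474 ± 630713 counts (mean ± SD) and 10 sham libraries with 8225528 ± 929919 counts. Totals did not differ by more than the spread between libraries (two-sided permutation p = 0.627). The mitochondrial share of counts was 2.53 ± 0.205% after lesion and 2.47 ± 0.284% in sham (permutation p = 0.607).

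Lesion libraries held counts of more genes. A count was found for 14890 ± 1022 genes in lesion libraries and for 11947 ± 854 genes in sham libraries, 24.6% more, and the lowest lesion library (13562 genes) lay above the highest sham library (13117 genes). The two-sided permutation p was 2e-05, the smallest that 100000 resamples can give (adjusted p = 3.5e-05 over 7 measures). With each library thinned to 7134670 counts the means were 14681 and 11768 genes. The 50 most abundant genes held 26.6 ± 2.13% of the counts after lesion and 31.8 ± 2.16% in sham (permutation p = 0.00016, adjusted p = 0.000224). Since the groups did not overlap in detected genes, the same holds within row A and within row B of the sample titles. This is no separate check of the row. Spearman correlations over genes had a median of 0.781 between lesion libraries, 0.696 between sham libraries and 0.701 between the groups, and lesion replicates 2 and 10 reached 0.933. No 2 libraries agreed within counting noise, since the smallest chi-square per degree of freedom of any pair was 64.0.

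**Figure D1:**
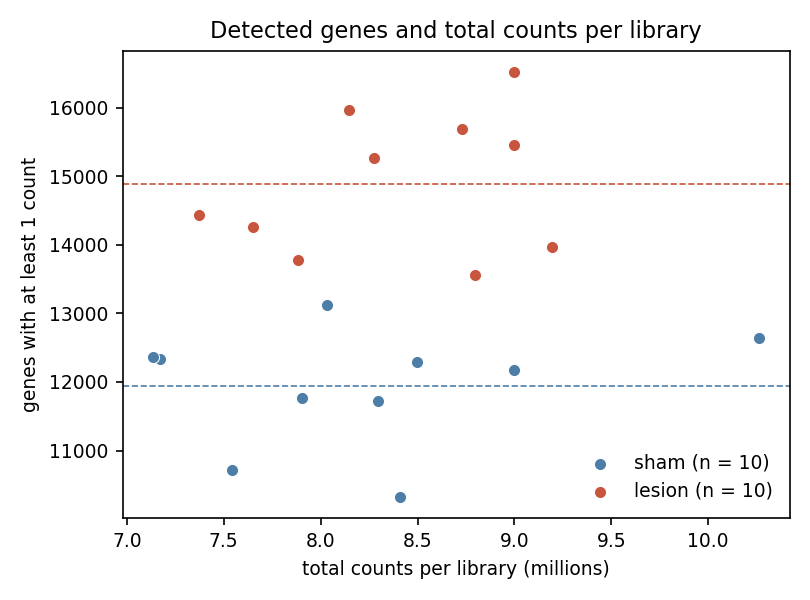
Total counts per library (x axis, scaled) and genes with at least 1 count (y axis) for 10 sham and 10 lesion libraries, with dashed lines at the group means of 11947 and 14890 genes. All lesion points lie above all sham points over a shared range of totals.

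Of 10467 genes tested, 454 were higher and 339 lower after lesion (edgeR quasi-likelihood test, adjusted p under 0.05), so that 57.3% of the calls were higher. This share depends on the method: it was 50.6% with DESeq2 size factors, 49.0% with the DESeq2 test, 72.0% with limma-voom and 78.6% without a filter. The change was at least 2-fold for 291 of the higher and 204 of the lower genes, and the median log2 fold change of all tested genes was 0.03. Row A alone gave 336 higher and 201 lower genes, and row B alone, with fewer libraries, 207 and 40. With the number of detected genes as a covariate, which nearly coincides with the group, 140 higher and 36 lower genes passed the threshold, and 138 and 29 of these were called without it too. Without lesion replicates 2, 9 and 10, which resemble each other, 321 were higher and 237 lower, and 318 and 230 of these were called with all libraries too.

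Neither OLIG2 nor SOX10, taken here as markers of the oligodendrocyte lineage, passed the test. OLIG2 (ENSDARG00000040946, chromosome 9, 32940682 to 32942789, GRCz10), the gene whose promoter drives the reporter, had 7490 ± 1352 CPM after lesion and 8302 ± 1163 CPM in sham. Its log2 fold change was -0.15 ± 0.11 (SE) with an edgeR adjusted p of 0.63. SOX10, a transcription factor of the oligodendrocyte and neural crest lineages, had 672 ± 86.5 and 719 ± 209 CPM (log2 fold change -0.10, edgeR adjusted p = 0.911). The gene olig1 (-0.35, edgeR adjusted p = 0.862) did not pass the test either; its log2 fold change ran from -0.54 to -0.22 with 1 library left out and from -2.48 to -0.13 over the other settings. The signs of OLIG2 and SOX10 differed between settings, as given with the processing results. In the oligodendrocyte progenitor list 1 of 27 members rose and 1 fell over all genes tested, and the same numbers held adjusted over the list alone. These were vcanb, a proteoglycan of the extracellular matrix (log2 fold change 1.05, not called without lesion replicates 2, 9 and 10), and GPM6A, a neural membrane glycoprotein, which fell from a mean of 5738 to 3259 CPM (edgeR adjusted p = 1.5e-07). The list was not called by camera (adjusted p = 0.772, and 0.919 with an estimated correlation), and its median of 0.25 was positive while the direction of the test was down; with detected genes as a covariate the list was called downward (adjusted p = 0.00883). PDGFRA, the platelet-derived growth factor receptor used as a progenitor marker, was not tested, with 2 counts in 1 lesion library and 156 counts in 1 sham library.

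No tested gene of the cell cycle list was called higher. Only 26 of its 66 matched genes, all 66 with a count, were tested. The others were below the filter and could not be called, so that a rise in these is not excluded. STMN1, which regulates microtubules and was among the most abundant genes, fell by 0.63 on the log2 scale (edgeR adjusted p = 0.00044), and SMC4, a condensin subunit, fell by 1.25. Among 26 tested members of the cell cycle list 0 rose and 2 fell over all genes tested, and the same numbers held adjusted over the list alone. The camera adjusted p was 0.394 (0.905 with an estimated correlation); the direction was up, and the median was 0.60. PCNA, a clamp of the replication fork, had a log2 fold change of 0.41 (edgeR adjusted p = 0.807), which ran from 0.04 to 0.80 with 1 library left out and from 0.20 to 2.40 over the other settings. The proliferation marker mki67 was too sparse for the test, with 1448 counts in lesion replicates 1, 5, 6 and 8 and 1 count in 1 sham library. These 4 libraries also shared nearly private genes: a median of 71.6% of such genes of 1 were seen in another of them (43.5 to 89.2% over 12 pairs). The median was 27.0% (5.88 to 83.3%) over 49 other pairs of lesion libraries, which leave out pairs among lesion replicates 2, 9 and 10. In those left out, 87.5 to 100% were seen where at least 8 genes were compared. Titles of replicates 1, 5, 6 and 8 end in columns 7 to 9, those of the other lesion libraries in columns 10 to 12. Position and this pattern therefore cannot be told apart. The 4 libraries were picked by their mki67 counts, and genes that go with mki67 can be nearly private to them. Their sharing is therefore no separate evidence for an effect of position or of the cell cycle. The list, with 19 of 26 members positive, was called upward without lesion replicates 2, 9 and 10 (camera adjusted p = 0.036), with detected genes as a covariate (adjusted p = 0.00185) and by fry (adjusted p = 0.0227).

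Myelin genes were among the most abundant, and the called members of the myelin list moved in both directions, more of them down. The myelin basic protein gene mbpa (ENSDARG00000036186, chromosome 19, 22229724 to 22248307) fell from 30587 ± 4757 to 14622 ± 3261 CPM, a log2 fold change of -1.06 ± 0.12 (edgeR adjusted p = 8.8e-07). Its paralog mbpb (ENSDARG00000089413, chromosome 16, 6862664 to 6909103) rose 4.86-fold from 602 ± 213 to 2925 ± 673 CPM (edgeR adjusted p = 3.2e-09). NFASC, an adhesion molecule of axon and glial contacts, fell from 371 ± 126 to 119 ± 36.3 CPM (edgeR adjusted p = 1.9e-05). TSPAN2, a tetraspanin, fell by 0.74 on the log2 scale. Of 29 tested members of the myelin list, 1 rose and 5 fell over all genes tested, cldnk, which is named after its values were seen, among the lower ones, and 1 rose and 8 fell adjusted over the list alone. The list was lower by camera (adjusted p = 0.00124), but not with an estimated correlation (adjusted p = 0.268) or with detected genes as a covariate (adjusted p = 0.909). The levels of cd59a, a complement regulator, were 41641 ± 9369 and 48984 ± 8164 CPM (edgeR adjusted p = 0.369). Reads shared between mbpa and mbpb may be divided by the counting, and the row B libraries alone did not call mbpa, NFASC or TSPAN2.

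The largest increases were in genes nearly silent in sham. The filter keeps such a gene only if it is found in about all lesion libraries, so that those found in fewer were not tested. The keratin gene krt8 (ENSDARG00000058358, chromosome 23, 10314656 to 10319318), which encodes an intermediate filament protein of simple epithelia, had 630 ± 173 CPM after lesion and 1 count in all sham libraries, a ratio of 51420 (95% counting interval 9229 to 2031000; edgeR adjusted p = 1.9e-18). The secreted factor NDNF was at 179 ± 72.7 CPM against 0.186 ± 0.120 CPM (edgeR adjusted p = 1.9e-13). The gene hapln1a, whose product links hyaluronan to proteoglycans, ranged from 15.9 to 192 CPM (SD 51.5) against 1 sham count, a ratio of 5011 (899 to 198000). CYP27C1, an enzyme of vitamin A metabolism, was at 186 ± 107 CPM, with 12 sham counts that all lay in sham replicate 9. Against the sham floor, crlf1a was at least 898-fold higher (332 ± 439 CPM) and clcf1 at least 117-fold; their products form a cytokine of the interleukin 6 family. The Notch ligand gene DLL1 was at least 262-fold higher (96.8 ± 79.0 CPM), the chemokine gene CXCL14 at least 99.2-fold, nfkbiaa, an inhibitor of NF-κB, at least 52.7-fold, and the Hippo pathway coactivator YAP1 at least 33.5-fold. These 10 genes were the largest increases under the fixed rule. In all, 11 genes were higher with at most 3 sham counts, 7 of them with none. The level of crlf1a ran from 3.54 to 1352 CPM among lesion libraries, its bound was 592-fold without the highest library, and its call was lost in limma-voom (adjusted p = 0.0813).

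**Figure D2:**
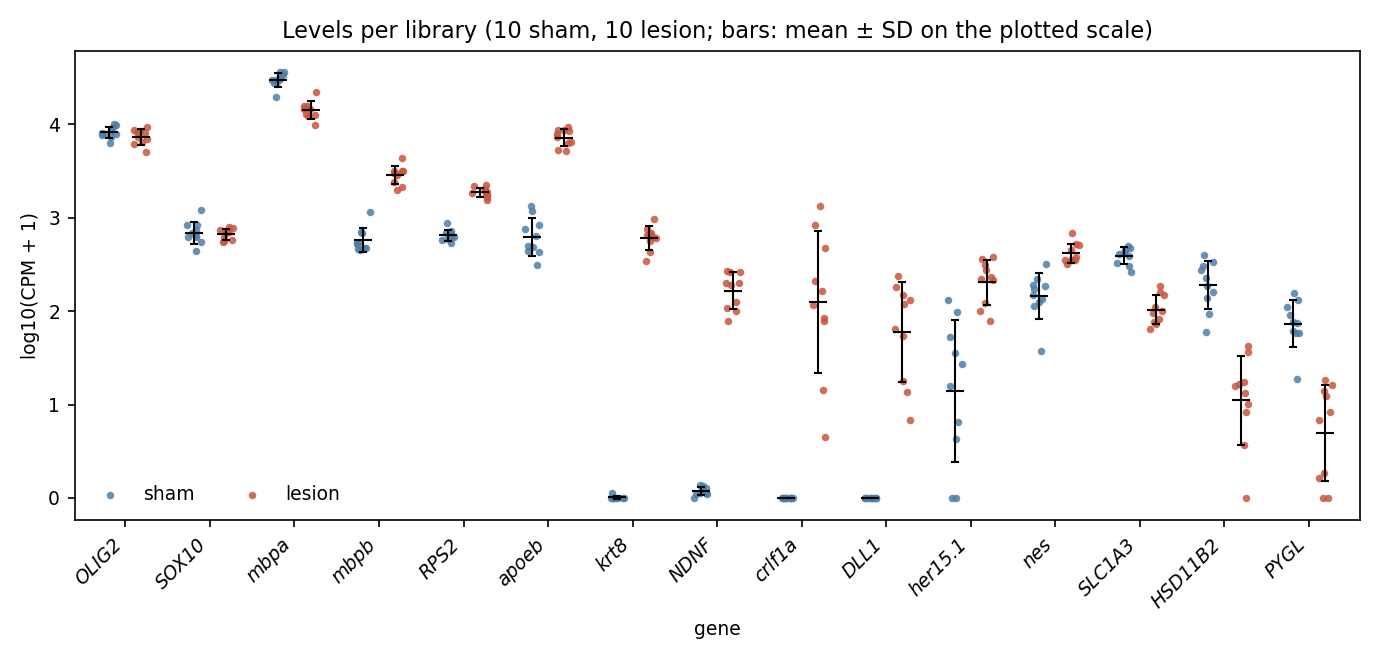
Levels of 15 named genes as log10(CPM + 1) (y axis) in each of 10 sham and 10 lesion libraries, with bars for the mean ± SD on that scale. OLIG2 lies near 8302 CPM in sham and 7490 CPM after lesion, whereas krt8 has 1 count in all sham libraries and a mean of 630 CPM after lesion.

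Nearly all genes of the cytosolic ribosome rose. Of 78 tested ribosomal protein genes 77 rose and 0 fell, over all genes tested as well as adjusted over the list alone, with a median log2 fold change of 1.23. RPS2 rose from 655 ± 93.9 to 1882 ± 219 CPM (edgeR adjusted p = 2e-10), RPL3 from 856 ± 149 to 2532 ± 351 CPM, rps20 by 1.80 and RPL26 by 1.26 on the log2 scale. Together these genes held 5.55 ± 1.23% of the counts after lesion and 2.38 ± 0.349% in sham (two-sided permutation p = 2e-05, the smallest possible). The camera adjusted p was 2.3e-100, and 0.0216 with an estimated correlation. The camera test with the preset correlation also called this list in 56 of 99 random splits of the 20 libraries; the estimated correlation between its genes was 0.674. Splits uneven in lesion libraries keep part of the lesion difference, so that this number does not measure false calls alone. Counts of near-identical copies of these genes cannot be separated with certainty.

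Genes of the Notch pathway and of neural progenitors rose in part. Of 15 tested Notch genes 5 rose and 0 fell over all genes tested, and 7 and 0 adjusted over the list alone. The 5 were the targets her12 (68.8-fold), her4.4 (33.7-fold) and her15.1 (6.28-fold, 229 ± 106 against 36.4 ± 44.8 CPM), the ligand gene dlb (31.5-fold) and the receptor gene NOTCH3 (21.0-fold). In edgeR their adjusted p-values were 0.0096, 0.0281, 0.0385, 0.0357 and 0.0398. Of these 5 only her12 kept its call without lesion replicates 2, 9 and 10. The Notch ligand gene DLL1, described above, kept its call in all 15 settings. It is not among the 15 tested Notch genes, because lists were matched by symbol and this list holds no gene of that name. Whether it is a listed gene under another name was not checked, so that the counts and tests of this list may lack a member. Single sham libraries set some of the folds: when 1 library was left out, the log2 fold change ran from 5.62 to 13.02 for her12, from 4.21 to 7.60 for her4.4, from 4.64 to 11.23 for dlb, from 4.15 to 5.41 for NOTCH3 and from 2.49 to 3.14 for her15.1. In the neural progenitor list 5 of 19 rose and 0 fell over all genes tested, and 6 and 0 adjusted over the list alone: nes, an intermediate filament of neural progenitors, from 164 ± 75.3 to 427 ± 114 CPM (edgeR adjusted p = 0.00051), mych from 357 ± 148 to 760 ± 143 CPM, SOX21 by 5.01 on the log2 scale (4.69 to 11.47 with 1 library left out), YAP1, and MYC, which is named here after its values were seen. SOX2, a factor of neural stem cells, had a log2 fold change of 0.80 (edgeR adjusted p = 0.0724) and was called in 2 of 20 fits that left out 1 library. Both lists were called by camera (adjusted p = 0.00124 for Notch and 0.00227 for progenitors), and both had an adjusted p of 0.0616 with an estimated correlation. When single libraries were left out, her15.1 and dlb were each called in 8 and NOTCH3 in 4 of 20 fits, with adjusted p up to 0.0672, 0.0792 and 0.072; her4.4 was lost without lesion replicate 7 (adjusted p = 0.11) and SOX21 without lesion replicate 9 (adjusted p = 0.0614) and without lesion replicates 2, 9 and 10.

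Inflammatory, stress and protein folding genes rose in part. The pieces of each group were dissociated together, so that effects of handling and of the lesion cannot be told apart. In the inflammatory list 4 of 23 rose and 0 fell over all genes tested, and 6 rose and 1 fell adjusted over the list alone; the 4 were clcf1, nfkbiaa, the kinase JAK1 (log2 fold change 1.12) and its inhibitor SOCS1 (1.14). The list was called by camera (adjusted p = 0.00697), but not with an estimated correlation (adjusted p = 0.187). Of 49 genes of the immediate early and dissociation stress list 10 rose and 0 fell over all genes tested, and 13 and 0 adjusted over the list alone (camera adjusted p = 0.00124, and 0.389 with an estimated correlation). They included JUNB (ENSDARG00000104773), a subunit of AP-1, from 363 ± 166 to 1224 ± 318 CPM (edgeR adjusted p = 7.1e-06), the chaperone gene HSPA8, from 1604 ± 394 to 3525 ± 292 CPM (edgeR adjusted p = 3.6e-07), and both GADD45B genes (ENSDARG00000013576 by 2.08 and ENSDARG00000027744 by 0.86 on the log2 scale). In the unfolded protein response list 3 of 31 rose and 0 fell over all genes tested and adjusted over the list alone, namely PDIA3 (0.76), atf4b (0.52) and HSPA5 (0.70), which act in the endoplasmic reticulum or its stress response (camera adjusted p = 0.038, and 0.281 with an estimated correlation). With detected genes as a covariate, the adjusted p was 0.0928 for the inflammatory list and 0.641 for both the stress and the unfolded protein response list. Without lesion replicates 2, 9 and 10 PDIA3 and HSPA5 lost their call. HSPA5 was called in 4 of 20 fits that left out 1 library (adjusted p up to 0.0943), and the call of the unfolded protein response list was lost without lesion replicate 2 (adjusted p = 0.0659) or sham replicate 5 (0.0524), 6 (0.0591) or 9 (0.0533).

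For antigen presentation, b2m, the light chain of class I molecules, rose from 150 ± 77.7 to 543 ± 153 CPM (edgeR adjusted p = 2e-04), and the proteasome activator genes PSME1 and PSME2 rose by 1.03 and 1.33 on the log2 scale. With irf9 (0.57) these were 4 of 32 members of the interferon list that rose, and 0 fell, over all genes tested and adjusted over the list alone. The calls of PSME2 and irf9 were lost in each row alone, and without lesion replicates 2, 9 and 10, as was that of AGRN. The list itself was not called by camera (adjusted p = 0.247, and 0.766 with an estimated correlation). In the extracellular matrix list hapln1a and AGRN (called in 14 of 20 fits that left out 1 library, adjusted p up to 0.0688) rose and SERPINE2, a protease inhibitor, fell by 0.90, which made 2 and 1 of 19 over all genes tested and adjusted over the list alone (camera adjusted p = 0.18, and 0.564 with an estimated correlation). The list was called in 6 of 20 fits that left out 1 library, with adjusted p down to 0.03.

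Genes of energy metabolism rose in part. Among 62 nuclear genes of oxidative phosphorylation 11 rose and 1 fell over all genes tested, and 17 and 1 adjusted over the list alone. The ATP synthase genes atp5f1e and ATP5PB rose by 0.87 and 0.64 and cox6a1 by 1.32 on the log2 scale, whereas COX4I2, an isoform of a cytochrome oxidase subunit, fell by 1.36 (edgeR adjusted p = 3.2e-06). The list was called by camera (adjusted p = 0.0281), but not with an estimated correlation (adjusted p = 0.564) or with DESeq2 size factors in place of TMM (adjusted p = 0.0985). Of 13 mitochondrially encoded genes MT-CO1 (lost without lesion replicate 3 or sham replicate 6, adjusted p = 0.0653 and 0.0536), MT-CO2 (0.52) and MT-CYB (0.43) rose and 0 fell over all genes tested, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.772, 0.919 with an estimated correlation, and 0.0292, upward, with detected genes as a covariate). In the hypoxia and glycolysis list 5 of 36 rose and 1 fell over all genes tested, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.211, and 0.641 with an estimated correlation). The glycolytic enzyme genes pgam1a and GAPDHS rose by 1.59 and 0.43 and PFKFB3, a regulator of glycolysis, by 0.82, whereas DDIT4, an inhibitor of mTOR signalling, fell by 2.52. In the cholesterol and fatty acid list ELOVL1 rose by 0.54 and the desaturase gene SCD fell by 1.38, 1 and 1 of 29 over all genes tested and adjusted over the list alone (camera adjusted p = 0.583, and 0.641 with an estimated correlation). Without lesion replicates 2, 9 and 10 MT-CO1, MT-CYB and GAPDHS lost their call. The call for oxidative phosphorylation was lost without lesion replicate 3 (adjusted p = 0.0873) or 6 (0.0536), or sham replicate 2 (0.0644), 5 (0.0602), 6 (0.0537), 8 (0.0949) or 9 (0.0769).

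The largest decreases were in genes of several functions. HSD11B2, which inactivates cortisol, fell from 217 ± 109 to 15.5 ± 13.2 CPM (edgeR adjusted p = 8.1e-05), a 14.0-fold lower level. DLG2, a scaffold protein, fell from 75.9 ± 35.8 to 4.67 ± 5.01 CPM (edgeR adjusted p = 0.00039), and PYGL, which breaks down glycogen, from 83.0 ± 40.1 to 7.19 ± 6.75 CPM (edgeR adjusted p = 0.00465). The secreted protein gene angptl7 fell from 211 ± 102 to 26.9 ± 42.1 CPM (edgeR adjusted p = 0.0077). The other 6 genes that the rule named were fam110d, palmdb, erv, OTUD7B, DLGAP1 and epdl1, with log2 fold changes from -4.90 to -2.94. With 1 library left out the log2 fold change ran from -3.24 to -1.60 for epdl1, from -3.50 to -1.99 for DLGAP1, from -4.41 to -3.53 for palmdb and from -3.93 to -2.81 for angptl7. Without lesion replicates 2, 9 and 10 the calls of OTUD7B, DLGAP1 and epdl1 were lost. The call of epdl1 held in 7 of 20 fits that left out 1 library (adjusted p up to 0.222), and that of DLGAP1 was lost without sham replicate 2 (adjusted p = 0.0655).

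Markers of other cell types moved in both directions or were below the filter. The ependymo-radial glia list had 7 of 29 higher and 3 lower genes over all genes tested, and 11 and 3 adjusted over the list alone (camera adjusted p = 0.18, and 0.619 with an estimated correlation), and was called in 4 of 20 fits that left out 1 library, with adjusted p down to 0.0191. VIM (ENSDARG00000010008), an intermediate filament, rose from 559 ± 129 to 1129 ± 317 CPM. The glutamate transporter gene SLC1A3 fell from 400 ± 78.8 to 109 ± 41.2 CPM (edgeR adjusted p = 4e-07) and GLUL (ENSDARG00000100003), which makes glutamine, from 3036 ± 819 to 1404 ± 281 CPM. In the microglia and macrophage list 1 of 8 rose and 0 fell over all genes tested and adjusted over the list alone: apoeb (ENSDARG00000040295, chromosome 16, 24045712 to 24048429), an apolipoprotein that glia also express, rose 10.7-fold from 691 ± 341 to 7393 ± 1495 CPM (edgeR adjusted p = 6.5e-10). The list was called by camera (adjusted p = 0.0489), but not with an estimated correlation (adjusted p = 0.187); leaving out lesion replicate 2 (adjusted p = 0.0659), 6 (0.0613), 8 (0.0555) or 10 (0.0527) or sham replicate 2 (0.071) or 5 (0.0557) also ended the call. Of 34 neuronal genes 2 rose and 0 fell over all genes tested and adjusted over the list alone, GNG3 (called in 17 of 20 fits that left out 1 library, adjusted p up to 0.0608, and not without lesion replicates 2, 9 and 10) and tubb5, a tubulin, from 79.1 ± 69.9 to 655 ± 283 CPM (camera adjusted p = 0.721, and 0.919 with an estimated correlation). With detected genes as a covariate the neuronal list was called downward (adjusted p = 3.4e-06). Of 6 muscle genes 0 rose and 0 fell over all genes tested, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.772, and 0.919 with an estimated correlation). In the skin list krt8 and icn, a calcium-binding protein (365 ± 500 against 3.16 ± 7.61 CPM), rose among 3 tested genes. The erythrocyte list had 2 tested genes, of which the carbonic anhydrase gene cahz fell by 1.09, the Schwann cell list 4, of which 1 fell, and the fibroblast and mural cell list 4, of which NOTCH3 rose. These 4 counts are over all genes tested and also hold adjusted over the list alone. No gene passed over all genes tested among 3 of the endothelium, 1 of the motor neuron and 1 of the neutrophil list, although 1 endothelial gene fell adjusted over the list alone, and 0 lymphocyte genes were tested. Below the filter, 13 of 14 motor neuron, 10 of 14 ependymo-radial glia, 12 of 24 neuronal and 16 of 34 microglia genes had counts in more lesion than sham libraries, and 0, 2, 2 and 6 in more sham libraries. In the other lists these numbers were 12 and 5 for endothelium, 8 and 3 for muscle, 5 and 2 for erythrocytes, 4 and 0 for Schwann cells, 8 and 6 for fibroblasts, 7 and 7 for skin, 5 and 6 for lymphocytes and 2 and 3 for neutrophils. The list totals include members without a count in any library, so that their shares cannot be set directly against the next one. Over all 13522 untested genes with a count, 63.6% had counts in more lesion and 23.8% in more sham libraries. Among them, named after their values were seen, were the motor neuron genes ISL1 (31.1 ± 50.7 CPM in 6 lesion libraries), MNX1 (20.6 ± 28.7 CPM in 5) and PRPH (18.1 ± 21.8 CPM in 8), each with 0 sham counts, and the leukocyte integrin gene itgb2 (68.8 ± 64.4 against 3.68 ± 11.6 CPM). These genes were not tested.

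The remaining lists were not called by camera with the preset correlation. Of 12 tested Wnt genes SFRP2, a secreted antagonist, fell by 1.68, and of 39 axon growth and guidance genes rtn4a rose by 0.44 (adjusted p = 0.0664 without lesion replicate 3) and EFNA1, an ephrin ligand, fell by 1.32, each over all genes tested and adjusted over the list alone. No gene was called among 15 of the FGF, 7 of the Hedgehog and 18 of the BMP and TGF-beta list, over all genes tested or adjusted over the list alone. The camera adjusted p was 0.947 for Wnt, 0.721 for FGF and 0.772 for the other 3 lists, and with an estimated correlation 0.963, 0.908 and 0.919. With detected genes as a covariate the axon growth list was called downward (adjusted p = 0.016). The direction of the Wnt test was down while its median (0.01) and mean (0.03) were positive, and for axon growth the mean (0.16) was positive while the median (-0.08) and the test were negative. The medians of the FGF, Wnt and endothelium lists change sign with the scaling.

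**Figure D3:**
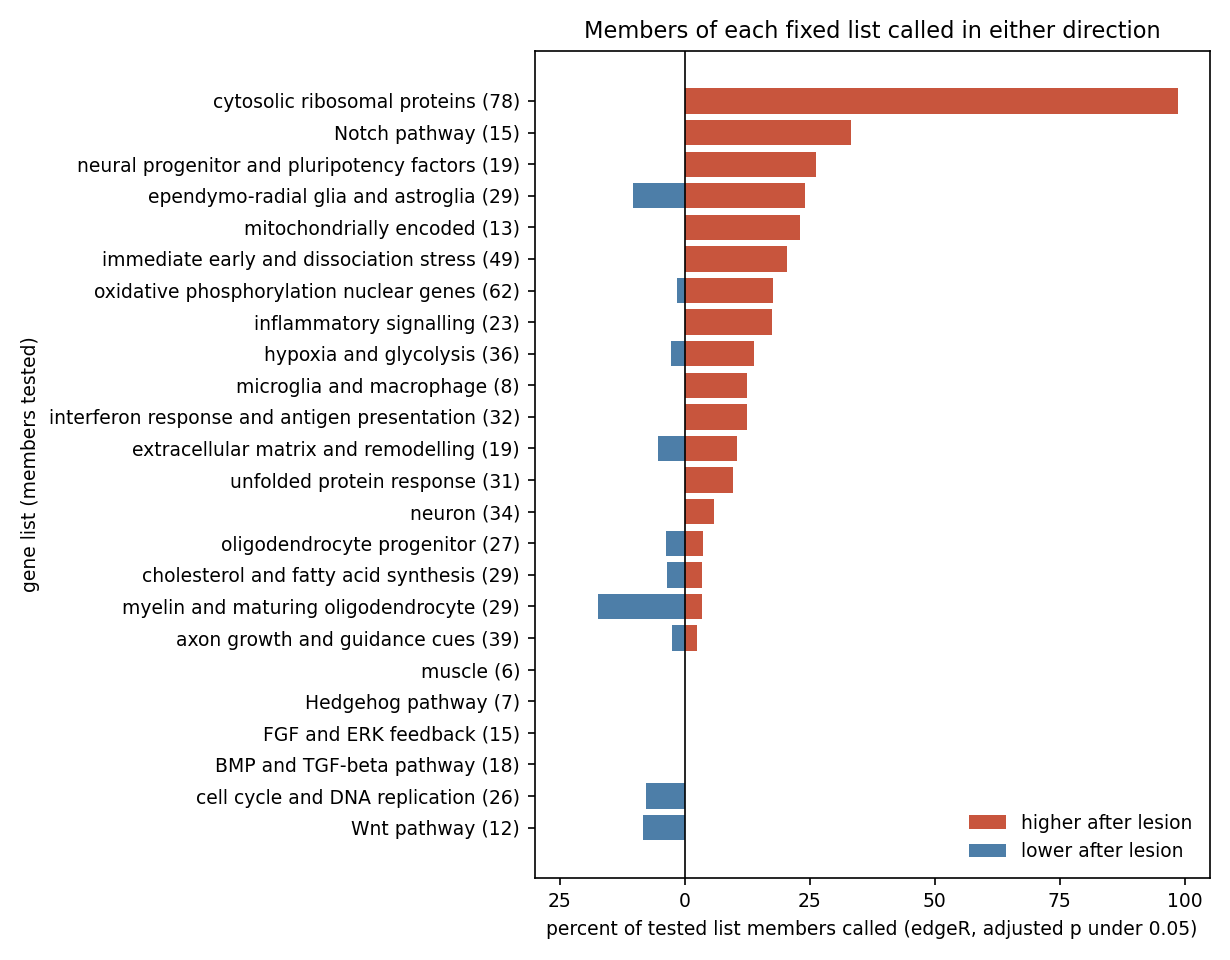
Percent of tested members (x axis) that were called higher (to the right) or lower (to the left) after lesion in edgeR, for each of the 24 fixed lists with at least 5 tested members (y axis, number tested in parentheses). Of 78 ribosomal protein genes 77 were higher, and no other list had more than 11 called in that direction.

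Camera called 9 of the 24 lists with the preset correlation, and only the ribosomal list with an estimated one. Of 99 random splits of the same libraries, 83 called at least 1 list with the preset correlation and the median was 2, so that this test passed its threshold more often than its adjusted p-values state. Among the called lists, the share of those splits that called them was lowest for microglia (1 of 99), inflammatory signalling (3) and the unfolded protein response (5), and higher for Notch (10), neural progenitors (11), oxidative phosphorylation (18), stress (22) and myelin (26).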

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

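The tests of depth, of skin cells, of carry-over between libraries and of a library deposited under 2 names were chosen after the results were seen; the random splits and the tests of dropout and of glia were set before their results.

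Chance in how these libraries fall into groups could be excluded for the counts of changed genes, but not a chance difference between 2 pools of cells, if the libraries of a group are portions of 1 pool. Of 100 splits of the 20 libraries into 10 and 10, only the real one, 1 split, called as many as 454 higher genes, and likewise only that 1 called as many as 339 lower genes; the highest other split called 34 in a direction, and 2 of the 99 others called any gene. For the number of lists called, 3 of the 100 splits, the real one included, reached 9, and the highest other split also called 9. That stays below the share set beforehand, which argues against such chance for the number. Other splits equalled the real one, so that it is not excluded.

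Lesion libraries held counts of more genes. Depth is argued against, since the difference was 2912.6 genes after thinning to equal totals, beyond the sham SD of 850 genes. Carry-over between lesion replicates 2, 9 and 10 is argued against too, because 2441 more genes were found without them (14388 ± 727, n = 7, exact permutation p = 0.000103). Less dropout, from more RNA or cells per lesion library, may contribute: of 5140 genes at 20 CPM or more in both groups, 81.4% varied less between lesion libraries (median coefficient of variation 0.373 against 0.545), with 78.1 to 82.5% when 1 library was left out and 77.5% without the 3 replicates. A wider range of genes in use after lesion also stays open and was not tested, as the number of cells per library is not given in the sources used here.

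The 11 genes that were higher with at most 3 sham counts raise the question of other cells among the sorted ones. Skin cells are argued against as the source of krt8, because 1 of 23 other listed skin genes, none of which is in another list, reached 63.0 CPM, 10% of its level, and 19 stayed under 1 CPM. Carry-over between lesion replicates 2, 9 and 10 was not decided by these genes. Their level in the other 7 lesion libraries had a median of 152.5% of that in the 3 (quartiles 94.7 and 191.6%, lowest 62.1%). The filter keeps genes this silent in sham only at a minimum level in about all lesion libraries. Genes high only in the 3 could not enter, so that the values show only that these 11 are not confined to the 3. A varying share of ependymo-radial glia, some of which could carry the reporter through the sort, stays open: over the 10 lesion libraries the mean level of these genes followed that of 29 glia genes with a Spearman's rho of 0.673 (permutation p = 0.04) and a Pearson's r of 0.550 (permutation p = 0.103), but without the 2 libraries farthest from the median rho was 0.571 (n = 8, exact permutation p = 0.151) and r 0.379, so that it depends in part on these. Expression in the oligodendrocyte lineage after lesion stays open as well and was not tested.

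Lesion replicates 2 and 10 resembled each other more than any other pair by rank correlation. A single library deposited as both is argued against by a chi-square of 68.1 per degree of freedom. Carry-over at a fixed ratio between replicates 2 and 10 is a candidate explanation: 13 genes nearly private to replicate 2 were all seen in replicate 10 at a median of 13.2% of its level, with an interquartile range of 8.88% of that median, against 81.0% or more in 32 other pairs. In the other direction 5 genes nearly private to replicate 10, fewer than the 8 asked of other pairs, were all seen in replicate 2 at a median of 17.55% (quartiles 14.15 and 17.94%), so that the direction stays open; replicates 2 and 10 also had 0 private genes, against 16 to 53 in the other lesion libraries. A fixed ratio is argued against for replicates 2 and 9, where that range was 191.7% of the median. The titles of replicates 9, 10 and 2 end in A10, A11 and A12, which would be neighbouring plate positions. An effect of position was not tested. Other labels set none of the 3 apart, so that no biological explanation was tested.

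Single libraries lay far from the rest of their group for 12 of 68 groups of values examined, 17.65%, where chance gives about 1 in 20. In 3 of these groups, of genes chosen as nearly silent in sham, 1 library held the only counts, which the rule must mark; of the other 65 groups 9 remained, 13.85%. Lesion replicate 3 was highest in angptl7 (142.7 CPM, next 34.1), in cd59a (63553 CPM, next 46124) and in mbpa (22193 CPM, next 15934). Lesion replicate 1 was highest in hapln1a (192 CPM, next 87.1) and lesion replicate 4 in mbpb (4374 CPM, next 3195). Sham replicate 8 was highest in mbpb (1152 CPM, next 707) and in SOX10 (1199.6 CPM, next 843), and held the only sham count of krt8 (0.143 CPM). Sham replicate 2 was lowest in mbpa (19811 CPM, next 28108) and highest in the ribosomal protein share (3.27%, next 2.48%). The sham counts of CYP27C1 all lay in sham replicate 9 (1.53 CPM) and that of hapln1a in sham replicate 7 (0.12 CPM).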

How the results depend on the processing

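The fits without lesion replicates 2, 9 and 10, or with these summed, were chosen after seeing the data. No alternative called a gene in the direction opposite to the reported one, and of 85 tested genes that the fixed rule selects and the text names all 79 called ones kept their sign in every fit that tested them; 67 kept their call in each of 20 fits without 1 library and 19 in each of the 15 settings. Calls were lost for 51 of 79 with detected genes as a covariate, 26 of 78 in row A, 49 in row B, 18 without the 3 replicates and 13 with these summed, and for 7 or fewer in each other setting. Genes named only after their values were seen are not in these counts. Higher and lower genes numbered 408 and 399 with DESeq2 size factors, 430 and 356 with TMMwsp, 470 and 320 with upper quartile scaling, 455 and 337 under the stricter filter, 455 and 341 in the robust fit, 459 and 332 with row as covariate, 456 and 337 after thinning, 321 and 237 without the 3 replicates, and 375 and 280 with these summed. Fits without 1 library gave 395 to 511 higher and 295 to 382 lower genes. Without a filter there were 2780 and 758 (median log2 fold change 0.21 over 23989 genes), with DESeq2 541 and 562, with limma-voom 1121 and 436 (median 0.69), with detected genes as a covariate 140 and 36, with row A alone 336 and 201, with row B alone 207 and 40, with adjusted p under 0.01 300 and 209, and with a fold of at least 2 291 and 204. The stricter thresholds lower the counts by construction. Smaller sets gave fewer calls for each row alone and without the 3 replicates, but more in some fits without 1 library. The cause of these and the other differences was not tested. The fit without low-detection libraries was not run, because 0 libraries met its rule. No paired analysis was possible because the replicate numbers are only names given in sample order.

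Camera called 1 list with an estimated correlation and fry, which tests a list's own movement, called 16, adding cell cycle (0.0227), interferon (0.00696), matrix (0.000611), hypoxia (0.00118), FGF (0.021), ependymo-radial glia (0.000932) and muscle (0.00696). The estimated correlation gave adjusted p of 0.268 for myelin, 0.187 for inflammatory and microglia, 0.389 for stress, 0.281 for the unfolded protein response, 0.564 for oxidative phosphorylation and 0.0616 for Notch and neural progenitors. DESeq2 size factors gave 0.0661 for the unfolded protein response, 0.0985 for oxidative phosphorylation and 0.0575 for microglia. With detected genes as a covariate 9 lists were called, 4 of them among the reported ones and 5 more (cell cycle 0.00185, oligodendrocyte progenitor 0.00883, axon growth 0.016, mitochondrially encoded 0.0292 and neuron), and adjusted p was 0.909 for myelin, 0.0928 for inflammatory, 0.641 for stress and unfolded protein response and 0.276 for microglia. The unfolded protein response and microglia lists had 0.078 and 0.104 without the 3 lesion replicates and 0.0659 and 0.127 with these summed. Over the fits without 1 library they ran from 0.0194 to 0.0659 and from 0.015 to 0.071, and oxidative phosphorylation from 0.0123 to 0.0949.

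Direction turned for lists not called. With fry these were oligodendrocyte progenitor (0.241), cholesterol (0.138), Wnt (0.18), Hedgehog (0.181), BMP (0.152) and axon growth (0.138). With DESeq2 size factors it was the mitochondrially encoded list (0.891). With detected genes as a covariate these were interferon (0.507), matrix (0.758), hypoxia (0.805), FGF (0.641) and neuron (3.4e-06, called downward). Without single libraries the direction turned in some fits for the mitochondrially encoded (0.684 to 0.9997), Wnt (0.844 to 0.9997), axon growth (0.773 to 0.9997), oligodendrocyte progenitor (0.684 to 0.99) and neuron (0.528 to 0.963) lists. Among uncalled genes, the log2 fold change with detected genes as a covariate was 0.15 for cd59a and 0.10 for OLIG2, and with row B alone 0.051 for OLIG2 and for SOX10. Without 1 library it ran from -0.16 to 0.014 for SOX10, positive only without sham replicate 8. The cause was not tested. Genes with counts in few libraries, such as mki67 and PDGFRA, were below the filter and were not tested.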

Other observations

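The test of glucocorticoid targets was set after the genes that raised it were seen but before the further targets were looked up, and the genes in this part were chosen after their values were seen.

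The 6 genes of translation or its control named next come from no fixed list, and no test of such a group was run. The elongation factor genes eef1a1l1 (log2 fold change 1.69, edgeR adjusted p = 2.9e-08), eef2b (1.45), EEF1G (1.41) and EEF1B2 (1.74), the poly(A)-binding protein gene pabpc1a (1.33) and TPT1 (1.82) were higher after lesion. The level of eef1a1l1 was 6482 ± 1175 CPM after lesion and 2002.5 ± 598 CPM in sham. Further genes had low sham levels: ANGPTL4, a secreted regulator of lipoprotein lipase, was at 433 ± 178 against 5.81 ± 12.9 CPM (edgeR adjusted p = 0.00072), lgals2a, a galectin, at 335 ± 143 against 3.1 ± 6.78 CPM, and txnb, a thioredoxin, at 193 ± 82.4 against 1.32 ± 3.76 CPM. FOXJ1, a transcription factor of motile cilia, rose by 7.47 on the log2 scale (edgeR adjusted p = 0.00048) with counts in 9 lesion and 3 sham libraries. Among the lower genes were gstr (-2.21, edgeR adjusted p = 6.5e-10), of the glutathione transferases, and GPT (-1.71, ENSDARG00000019541), an aminotransferase.

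Genes known to respond to glucocorticoids or to handle them were lower after lesion: FKBP5 (-1.41, edgeR adjusted p = 1.1e-06), tsc22d3 (-0.87), DDIT4 (-2.52), HSD11B2 (-3.81) and GLUL (-1.11, ENSDARG00000100003). A lower glucocorticoid response after lesion is a candidate explanation, and it would lower other targets too. Of 15 tested genes on a further list of 20 target symbols, 8, or 53.3%, had a negative log2 fold change (exact sign test p = 1). IRS2 (ENSDARG00000037099) fell by 1.79 and sgk1 rose by 0.65. The test did not decide, since the targets went both ways, and the hypothesis stays open.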
